A study of Mus musculus with 12 samples.

How the data were processed

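The samples were mouse embryonic fibroblasts carrying a doxycycline-inducible cassette for the reprogramming factors Oct4 (Pou5f1), Klf4, Sox2 and c-Myc (OKSM) and a reverse tetracycline transactivator. Per the labels' protocols, the cells were infected with a retroviral hairpin against Chaf1a or against Renilla luciferase, and the factors were induced with doxycycline for 3 or 6 days in serum and LIF. RNA from 4 groups of 3 samples was labelled with biotin from 100 ng of RNA and hybridised to Affymetrix mouse arrays, per the labels' protocols. The labels name the molecule as polyA RNA and the extraction as total RNA. They do not say whether replicates came from separate embryos or cultures, so the p-value of a gene measures only the spread between these samples. No scan date or batch is given, and the genome build and annotation version of the array are not given in the sources used here.

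The deposited values are signal intensities normalised by RMA in Affymetrix Expression Console 1.3.0.187, per the submitters' processing notes, which do not give the version of RMA. The plan written beforehand took the deposited values to be log2 values, but they ran from 4.71 to 13421, which is a linear intensity scale. The log2 of each intensity was therefore taken, and no other transformation was made. The file held 41345 probe sets for 12 arrays with no missing value. Of these, 23521 named 1 gene, 1814 named several genes and 16010 named none. Gene names were used as the file pairs them with probe sets, and 23328 probe sets had a gene ID found in the reference gene table. The 1-gene probe sets covered 22180 genes, of which 1082 had several probe sets, and the probe set with the highest mean over the 12 arrays stood for such a gene. Probe sets naming several genes or none were fitted only in a separate check. The median intensity per array was 39.5 to 43.3, and Pearson's r between arrays of the same group was 0.992 to 0.995. The number of arrays limits the precision.

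A probe set was kept when it reached the array's own 30th percentile, which lay between log2 values of 4.30 and 4.38, in at least 3 arrays, which left 17860 genes. Differences were tested with limma 3.58.1 in R 4.3.3, with a mean per group over all 12 arrays, 8 residual degrees of freedom and 4.37 prior degrees of freedom, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The comparisons were knockdown against control at day 3 and at day 6, the difference between those effects, day 6 against day 3 within control and within knockdown, and the knockdown effect averaged over both days. Errors beside a mean are SDs over 3 arrays, and SE is the standard error of a fitted log2 fold change. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and plots with matplotlib 3.10.9.

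Gene lists numbering 26, with 611 different members that had a probe set of their own before the low-value filter, were fixed before the data were examined. They covered CAF-1 and other histone chaperones, reprogramming factors, the core pluripotency network, epithelial genes, fibroblast and mesenchymal genes, two-cell-like genes, DNA replication, mitosis, p53 targets, senescence and the Cdkn2 locus, interferon-stimulated genes, DNA methylation and heterochromatin, germline, primitive and definitive endoderm, trophoblast, neural, muscle, adipocyte, cartilage and bone, macrophage and leukocyte, endothelial, keratinocyte, TGF-beta-responsive genes, glycolysis, oxidative phosphorylation, and the unfolded protein and amino-acid stress response. Each was tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 26 lists, and again with an estimated correlation. With the preset correlation, camera sets a list's genes against other genes and does not measure how a list score varies between arrays. The test fry asked whether a list's own genes moved on balance in a single direction. A list score is the mean over members of the log2 value after subtracting each gene's mean over the 12 arrays. Members were also counted with p-values adjusted over the list alone.

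The genes named were chosen by a rule written before the data were examined. For each knockdown comparison it takes Chaf1a, Chaf1b, Pou5f1, Sox2, Klf4 and Myc, and the 10 largest rises and 10 largest falls past the threshold with all 3 knockdown arrays on the same side of all 3 control arrays. Where fewer than 5 genes of a direction passed, it takes the 5 with the smallest p in that direction, said not to pass. Each time comparison gives 10 rises and 10 falls, and the difference between days 5 of each sign. For a gene list, the rule takes up to 4 members past the threshold, and where fewer than 2 passed, the 2 with the highest level. Genes with a predicted Gm or Rik name, or an RNA gene name of the Mir, Snord, Snora, Rn or n-R type, were not named.

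Groups share replicate numbers. After the group means were removed, all 12 same-number pairs of arrays in compared groups correlated by more than 0.1 (0.137 to 0.373), and in each pair the correlation exceeded those with other numbers, so the numbers pair the samples. The planned fit had no block for the replicate number, and a fit with that block was an alternative. Of the list tests, only camera with the preset correlation was rerun with the block. The estimated correlation and fry were run without it, so their results leave the pairing out. Leaving out arrays, no low-value filter, a 50th percentile filter, repeated quantile normalisation, median centring, a fit of only the groups compared, an intensity trend with robust estimation, array weights, the mean of a gene's probe sets, a 1.5-fold minimum and an adjusted p of 0.01 were the other alternatives. Leaving out replicate 2 of both day 3 groups and replicate 1 of both day 6 groups was added after seeing the data.

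The procedure was tested on simulated data for the 17860 genes with 200 changed, 50 at each of 4 sizes. For the day 3 comparison it recovered 68% of changes of 0.5 log2 units and 98% of changes of 1, with 5.18% of its calls on unchanged genes. For the day 6 comparison it recovered 84% and 98%, with 5.45% of calls on unchanged genes. For the control time course the shares were 78% and 98%, with 5.05% of calls on unchanged genes. For the difference between days they were 34% and 96%, with 2.94%. Changes of 1.5 or 2 were recovered in all cases, and an epithelial list shifted by 0.3 was called in each of the 4 comparisons with 0 of 25 other lists. The simulated noise was independent for each gene and array, without correlation between genes or pairing by replicate number. The simulation therefore cannot show how often the gene and list tests make false calls in the real data.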

Results

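Gene expression was measured on 12 microarrays in mouse embryonic fibroblasts during the first days of OKSM-induced reprogramming, with a hairpin against Chaf1a or a control hairpin against Renilla luciferase. There were 3 arrays for each hairpin at day 3 and 3 at day 6. Chaf1a encodes the large subunit of CAF-1, the histone chaperone that deposits histones on newly replicated DNA. The series asks how its depletion changes expression early in reprogramming. The first principal component held 49.6% of the variance over genes, the second 10.2% and the third 8.08%.

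The targeted transcript was lower in knockdown arrays at both days, by little and without passing the test. Chaf1a stood at a log2 intensity of 7.53 ± 0.17 (SD, n = 3) in day 3 controls and 7.24 ± 0.09 in day 3 knockdown arrays, which is 1.22-fold lower. At day 6 the levels were 7.22 ± 0.14 and 7.10 ± 0.06, or 1.09-fold lower. The knockdown array was the lower in 3 of 3 same-number pairs on each day, and the groups did not overlap at day 3. The adjusted p-values were 0.726 and 0.999, and the 95% interval of the log2 fold change was −0.49 to −0.08 at day 3 and −0.32 to 0.09 at day 6. With arrays left out the day 3 difference ran from −0.34 to −0.16, the smallest without replicate 2 of both groups, and the day 6 difference from −0.20 (without control replicate 1) to −0.07 (without control replicate 3). Chaf1b, the middle subunit of CAF-1, was lower by a log2 fold change of −0.43 (SE 0.10, adjusted p = 0.697) at day 3 and −0.20 (SE 0.10, adjusted p = 0.999) at day 6, where it was −0.33 without control replicate 1 and −0.11 without control replicate 2. CAF-1 protein was not analysed here.

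**Figure D1:**
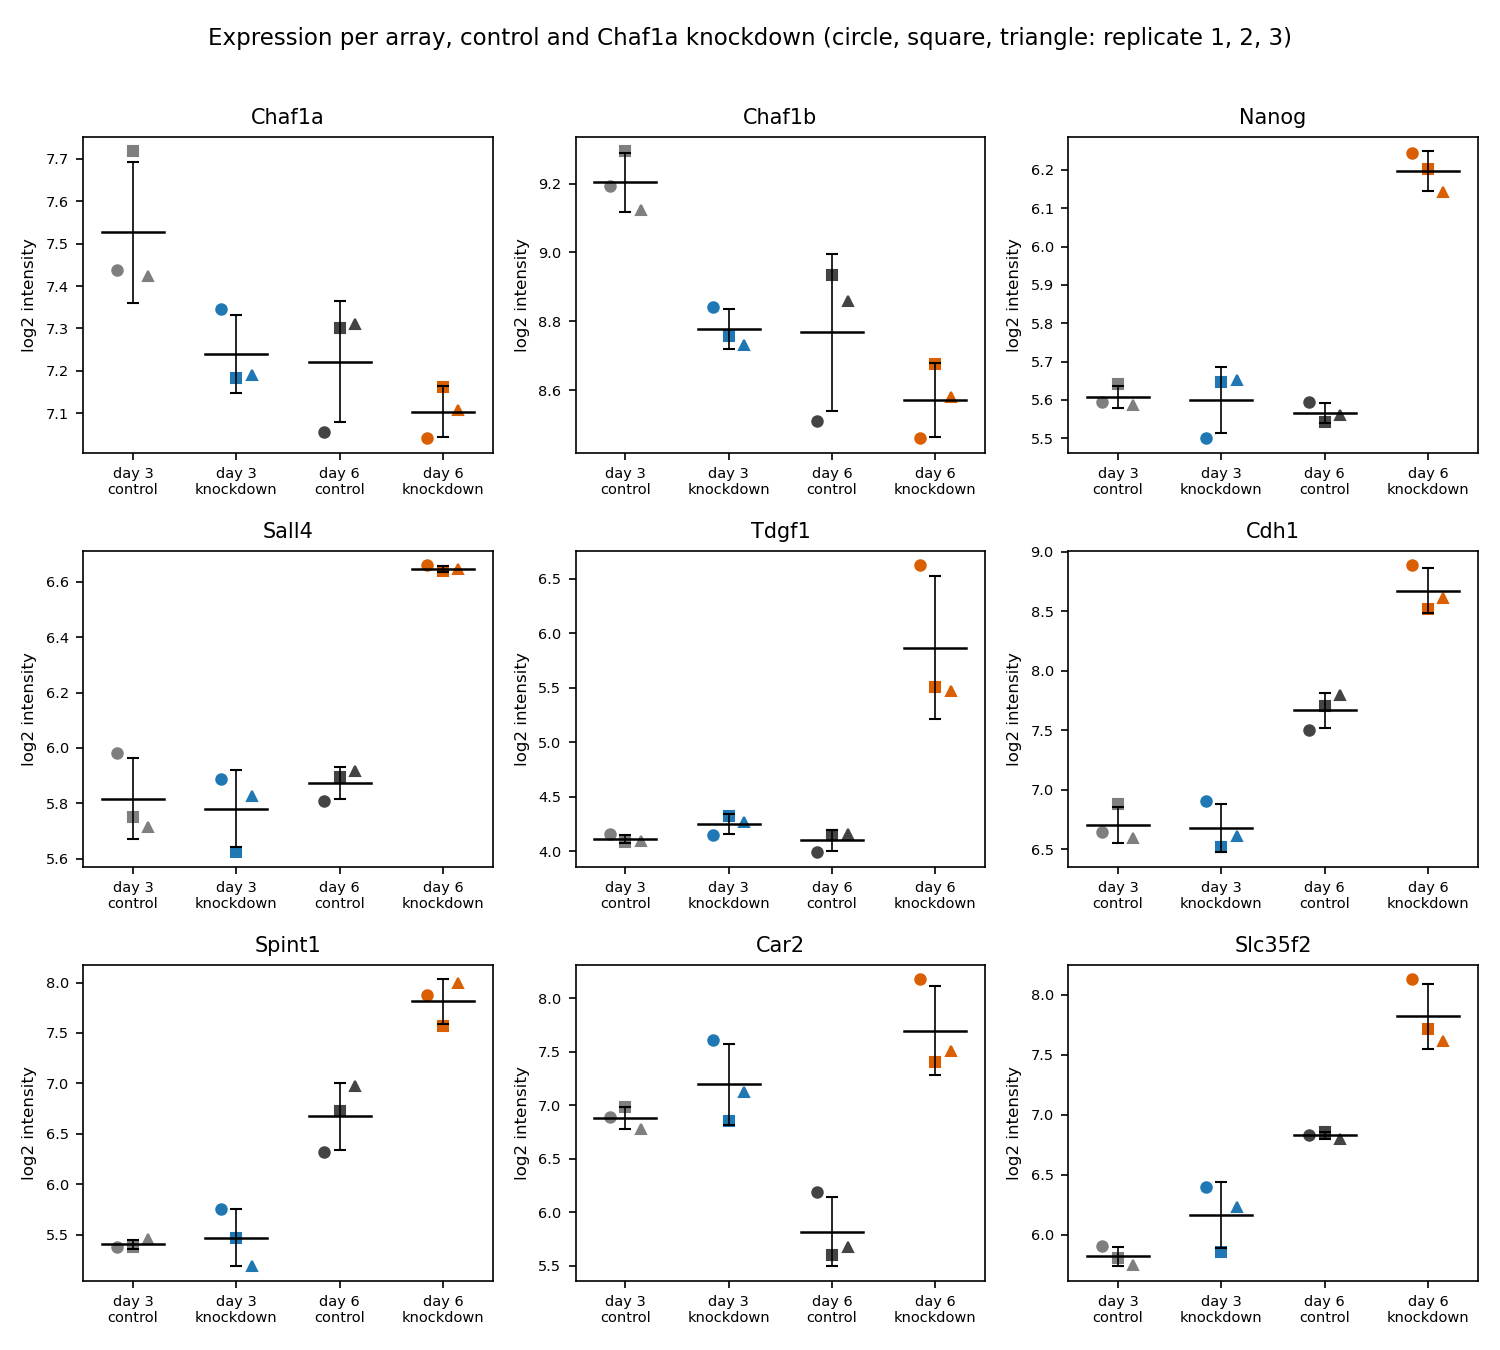
Log2 intensity of Chaf1a, Chaf1b and the 7 genes that passed the day 6 knockdown test, by group on the x axis. Each symbol is an array, lines are group means and bars are SDs (n = 3). Nanog was at 6.20 in day 6 knockdown arrays and 5.57 in day 6 controls.

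At day 6, pluripotency and epithelial genes were higher in the Chaf1a knockdown cells. Of 17860 genes, 7 rose and 0 fell at an adjusted p of 0.05, and 4 of the 7 rose at least 2-fold. Nanog, a transcription factor of the pluripotency network, rose 1.55-fold, from 5.57 ± 0.03 (SD, n = 3) to 6.20 ± 0.05 (adjusted p = 0.00261). Sall4, another pluripotency transcription factor, rose 1.71-fold, from 5.87 ± 0.06 to 6.65 ± 0.01 (adjusted p = 0.00589). Tdgf1, a co-receptor for Nodal made by embryonic stem cells, rose from 4.10 ± 0.09 to 5.87 ± 0.65 (adjusted p = 0.0130). Its control level lay below the low-value filter, so its ratio of 3.41 was taken against background signal. Cdh1, which encodes E-cadherin, rose 2.01-fold from 7.67 ± 0.15 to 8.67 ± 0.19 (adjusted p = 0.0130). Spint1, an inhibitor of epithelial serine proteases, rose 2.20-fold from 6.68 ± 0.33 to 7.81 ± 0.22 (adjusted p = 0.0435). Car2, a carbonic anhydrase, rose 3.68-fold from 5.82 ± 0.32 to 7.70 ± 0.42 (adjusted p = 0.010), and Slc35f2, a solute carrier, 1.99-fold from 6.83 ± 0.03 to 7.82 ± 0.27 (adjusted p = 0.0291). For all 7, each knockdown array lay above each control array.

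No gene was lower past the threshold at day 6 in limma. At an unadjusted p of 0.05 there were 793 genes, 384 higher and 409 lower, where chance gives 893, and 10.6% of genes had groups that did not overlap, where chance gives 10%. Both chance figures take the arrays as unpaired. The pairing by replicate number would lower them, so these counts cannot show that there is no effect beyond chance. The 5 genes with the smallest p among those lower did not pass. They were Col2a1 (log2 fold change −0.44, adjusted p = 0.148), a cartilage collagen, Lef1 (−0.31, 0.262) and Pygo1 (−0.42, 0.292), both of the Wnt pathway, Fmn1 (−0.29, 0.309), a formin, and Gapdhs (−0.36, 0.318), a sperm glycolytic enzyme. Over the alternatives Fmn1 ran from −0.335 to −0.173. Nanog passed in all 7 settings that left out arrays and all 9 others. Sall4 passed in 6 of those 7, Car2 in 5, Cdh1 and Tdgf1 in 4, Spint1 in 2 and Slc35f2 in 1. All 7 stayed higher there, with lowest log2 fold changes of 0.61 for Nanog, 0.74 for Sall4, 1.64 for Car2, 0.82 for Cdh1, 1.34 for Tdgf1, 0.93 for Spint1 and 0.84 for Slc35f2. Of the 9 others, Spint1 passed in 5 and Sall4, Car2, Cdh1, Slc35f2 and Tdgf1 in 8 each. Spint1 did not pass with the replicate block (adjusted p = 0.0820), array weights, renewed quantile normalisation or only the 2 groups compared, and Car2, Cdh1, Slc35f2 and Tdgf1 did not pass with only those 2 groups. With the mean of its probe sets Sall4 rose by 0.36 and did not pass (adjusted p = 0.281), its other probe set lying at 3.83 on average with −0.06 at day 6. Cdh1 rose by 0.65 in that setting and passed. The count was 3 without control replicate 1, 2 without control replicate 2, 4 without control replicate 3 and 4 without replicate 1 of both groups.

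The core pluripotency network moved up as a group at day 6. Of 42 members measured, 3 rose (Tdgf1, Sall4 and Nanog), 0 fell and 39 did not pass, and adjusted over the list alone 7 rose and 0 fell. The other 4 of those 7 were Nodal, Nr5a2, Nr0b1 and Utf1, named after their values were seen, with log2 fold changes of 0.34, 0.45, 1.39 and 0.87. The list's mean log2 fold change was 0.22, with 32 members positive (camera adjusted p = 1.52e-13, and 8.14e-04 with an estimated correlation). Scores per array ran from 0.23 to 0.28 in knockdown and from 0.02 to 0.06 in control. Of 36 epithelial genes, 2 rose (Spint1 and Cdh1), 0 fell and 34 did not pass, and adjusted over the list alone 12 rose and 0 fell. Among these, named after their values were seen, Epcam had a log2 fold change of 1.11 and Dsp, which encodes desmoplakin, 0.64. The list's mean was 0.24, with 29 members positive (adjusted p = 4.66e-14, and 0.00158 with an estimated correlation). Its scores ran from 0.22 to 0.26 in knockdown arrays and from −0.03 to 0.05 in controls.

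The signal of the probe sets for the 4 induced factors differed little between hairpins, which does not measure induction of the cassette. At day 6 the log2 fold change was 0.05 for Pou5f1, 0.02 for Sox2, 0.04 for Klf4 and −0.04 for Myc (each adjusted p = 0.999), and at day 3 it was −0.06, −0.05, 0.04 and 0.17 (adjusted p from 0.859 to 0.963). The 95% intervals at day 6 were −0.08 to 0.19, −0.18 to 0.22, −0.09 to 0.17 and −0.23 to 0.15. The sources used here do not say whether these probe sets read the cassette, the endogenous gene or both. Sox2 lay at 4.76 on average, below every array's median of at least 5.30. The list of 4 factors was not called at day 3 (adjusted p = 0.808) or day 6 (adjusted p = 0.596).

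**Figure D2:**
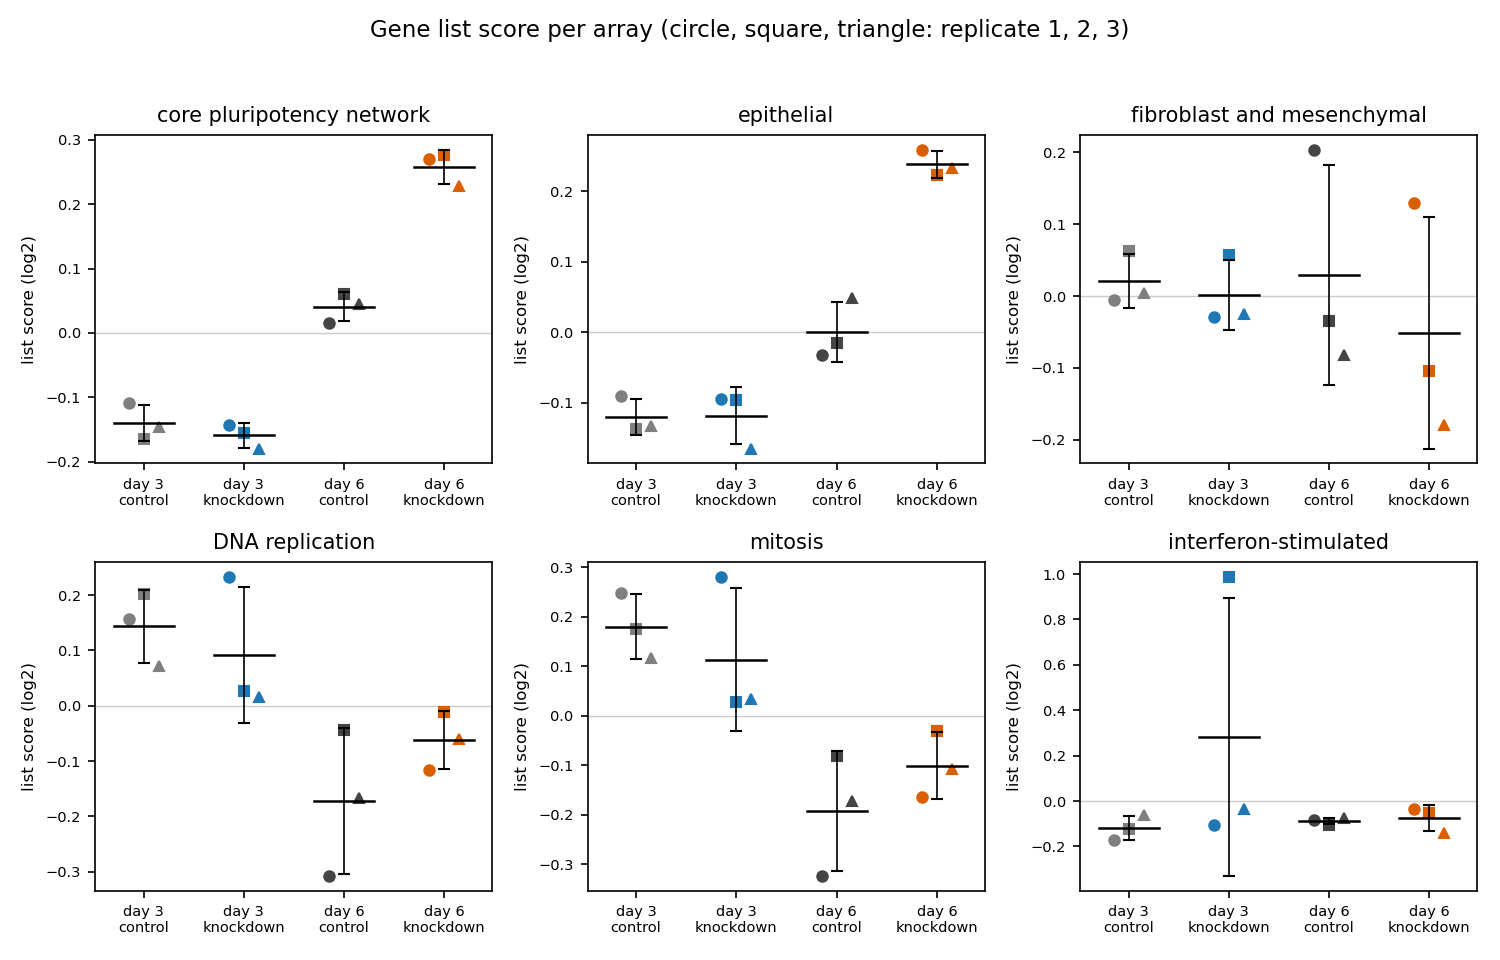
Scores of 6 gene lists (mean log2 value relative to each gene's mean over the 12 arrays) by group on the x axis. Each symbol is an array, lines are group means and bars are SDs (n = 3). At day 3 the interferon score of knockdown replicate 2 was 0.99, and day 6 control replicate 1 had the lowest DNA replication score, −0.31.

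Proliferation genes also lay higher at day 6, but not past the test with an estimated correlation. Of 35 DNA replication genes 0 passed, also adjusted over the list alone, with a mean log2 fold change of 0.11 and 32 positive (adjusted p = 4.98e-08, but 0.593 with an estimated correlation). Pcna stood at 0.10 and Rrm1 at −0.04. Of 31 mitosis genes 0 passed by either count, with a mean of 0.09 and 28 positive (adjusted p = 4.67e-06, but 0.644 with an estimated correlation), Mki67 at 0.14 and Anln at 0.12. Day 6 control replicate 1 had scores of −0.31 for replication and −0.32 for mitosis, the lowest of the 12 arrays, and without it the means were 0.04 (adjusted p = 0.0540) and 0.03 (adjusted p = 0.236). Knockdown replicate 1, its partner, was the lowest of the knockdown arrays on that day (−0.12 and −0.17). Without replicate 1 of both groups the means were 0.07 (adjusted p = 6.47e-04) and 0.06 (adjusted p = 0.00324), and the knockdown array was the higher in 3 of 3 pairs for both lists. With arrays left out the means reached 0.17 and 0.15, without control replicate 2. Control replicate 1 had the highest fibroblast and mesenchymal score, 0.20. That list had a mean of −0.08 with 38 of 40 members negative and 0 past the threshold by either count, Vim at −0.05 and Thbs1 at −0.07 (adjusted p = 0.00174, but 0.644 with an estimated correlation). Without control replicate 1 its mean was 0.01 (adjusted p = 0.990), without knockdown replicate 2 −0.05 (adjusted p = 0.0992), and without knockdown replicate 3 −0.02 (adjusted p = 0.494). It was −0.08 (adjusted p = 0.00246) without replicate 1 of both groups, and the knockdown array was the lower in 3 of 3 pairs. Without knockdown replicate 1 alone it was −0.17.

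Smaller shifts at day 6 reached 3 more lists, each lost with an estimated correlation (adjusted p = 0.457 for each). DNA methylation and heterochromatin genes had a mean of 0.07, with 0 of 27 past the threshold and 1 adjusted over the list alone, Jarid2 at 0.36 (adjusted p = 0.00129; mean 0.04 and 0.120 without control replicate 1, and 0.04 and 0.0778 without replicate 1 of both groups). The members with the highest level were Cbx3 at −0.04 and Trim28 at 0.08. Glycolysis genes had a mean of 0.07, with 0 of 16 past the threshold and 1 adjusted over the list alone, Slc2a1 at 0.25 (adjusted p = 0.0283). That call was lost without control replicate 1 (mean 0.06, adjusted p = 0.120), control replicate 2 (0.06, 0.111), knockdown replicate 1 (0.05, 0.148), knockdown replicate 3 (0.07, 0.247) or replicate 1 of both groups (0.04, 0.216), and also with array weights (0.06, 0.0524) or the mean of probe sets (0.05, 0.194). Gapdh stood at 0.01 and Pkm at 0.05. Unfolded protein and amino-acid stress genes had a mean of −0.08, with 0 of 22 past the threshold by either count, Hsp90b1 at −0.06 and Canx at −0.03 (adjusted p = 0.00461; mean −0.06 and 0.162 without knockdown replicate 2). Jarid2 and Slc2a1 were named after their values were seen.

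The remaining lists were not called at day 6. Their mean log2 fold changes were 0.04 for CAF-1 and other chaperones (adjusted p = 0.0616), 0.04 for two-cell-like genes, −0.02 for p53 targets and −0.05 for senescence and the Cdkn2 locus. For other lineages they were −0.00 for germline, 0.01 for endoderm, 0.05 for trophoblast, −0.01 for neural, −0.02 for muscle, −0.02 for adipocyte, −0.05 for cartilage and bone, 0.03 for macrophage and leukocyte, −0.02 for endothelial and 0.01 for keratinocyte genes. TGF-beta-responsive genes stood at −0.04 and oxidative phosphorylation at −0.01. Interferon-stimulated genes had a mean of 0.01 (adjusted p = 0.992). Adjusted over the list alone, the trophoblast list held 1 gene higher (Tfap2c, 0.55), the keratinocyte list 1 higher and the cartilage list 1 lower (Col2a1), the first named after its value was seen. Mean, median and test differed in sign for the interferon, germline, endoderm and oxidative phosphorylation lists.

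At day 3, no gene differed between hairpins past the threshold. In limma 0 of 17860 genes passed, against 1074 at an unadjusted p of 0.05 (557 higher, 517 lower), where chance gives 893. The groups did not overlap for 10.8% of genes, where chance gives 10%. Both chance figures again take the arrays as unpaired. Of the 7 day 6 genes, Nanog (log2 fold change −0.01), Sall4 (−0.04) and Cdh1 (−0.03) were near equal in both groups. Slc35f2 (0.34, adjusted p = 0.765), Car2 (0.31, 0.899), Tdgf1 (0.13, 0.961) and Spint1 (0.07, 0.979) lay higher in knockdown arrays without passing. Slc35f2 was higher in 3 of 3 same-number pairs. The smallest adjusted p was 0.545. The 5 highest-ranked genes in each direction did not pass. Those higher were Tcl1b2 (0.35), Gnrh1 (0.39), Rnf26 (0.34), Zfp113 (0.35) and Adamtsl5 (0.35). Those lower were Kmt2c (−0.41), a histone methyltransferase, Krt40 (−0.32), Entpd7 (−0.30), Chaf1b (−0.43) and Rprl2 (−0.33). Over the alternatives Rnf26 ran from 0.06 to 0.35 and Entpd7 from −0.35 to −0.19. The median 95% interval of a log2 fold change extended 0.18 to either side. Neither probe sets naming several genes nor those naming none gave a call at day 3 (smallest adjusted p = 0.332) or day 6 (0.132). In that fit of all 41345 probe sets together, only 3 that named 1 gene passed at day 6 (smallest adjusted p = 0.0204), against 7 genes in the main fit.

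Interferon-stimulated genes were high at day 3 in 1 knockdown array. Replicate 2 had a score of 0.99, and the other 11 arrays lay between −0.17 and −0.03. Bst2, an antiviral membrane protein, was at 10.64 in that array and at 8.43 to 8.71 in the other day 3 knockdown arrays. Of 26 members 0 passed, also adjusted over the list alone, and 25 were positive, with a mean of 0.40 (adjusted p = 3.74e-09, but 0.849 with an estimated correlation). Bst2 had a log2 fold change of 0.85 and Ifitm3 of 0.24. Without that array the mean was 0.05 (adjusted p = 0.347), and without replicate 2 of both groups it was 0.05 (adjusted p = 0.476).

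Chaperone, heterochromatin and mitosis genes lay slightly lower at day 3. Of 17 genes for CAF-1 and other chaperones 0 passed, and adjusted over the list alone 1 was lower, Chaf1b; the mean was −0.08 (adjusted p = 0.0248, but 0.962 with an estimated correlation), with Rbbp7 at −0.03 and Nap1l1 at 0.00. DNA methylation and heterochromatin genes had a mean of −0.06 with 0 of 27 past the threshold by either count (adjusted p = 0.0241, but 0.849 with an estimated correlation), Cbx3 at 0.05 and Trim28 at −0.05. Mitosis genes had a mean of −0.07 with 0 of 31 past the threshold by either count (adjusted p = 0.0376, but 0.962 with an estimated correlation), Anln at −0.08 and Mki67 at −0.05. The knockdown array was the lower in 2 of 3 pairs for chaperones and mitosis and in 3 of 3 for heterochromatin. With arrays left out the 3 means kept their sign, and calls were lost in 5 fits, some with means about as large. Without control replicate 1 the means were −0.09 for chaperones (adjusted p = 0.0577), −0.06 for heterochromatin (0.167) and −0.03 for mitosis (0.624), and without control replicate 2 −0.05 (0.321), −0.05 (0.0525) and −0.07 (0.0525). Without knockdown replicate 2 they were −0.05 (0.582), −0.05 (0.347) and −0.02 (0.739). Without knockdown replicate 3 they were −0.08 (0.0529) for chaperones and −0.03 (0.821) for mitosis, and without replicate 2 of both groups −0.02 (0.788), −0.03 (0.476) and −0.03 (0.667). Without knockdown replicate 1 the mitosis mean was −0.15. Array weights also ended the 3 calls (means −0.06, −0.05 and −0.06, adjusted p = 0.172, 0.119 and 0.119), and renewed quantile normalisation that of mitosis (−0.06, adjusted p = 0.0711).

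The other lists were not called at day 3. DNA replication, cartilage and bone, and macrophage and leukocyte genes came nearest, with means of −0.05, −0.07 and 0.07 (adjusted p = 0.0876 each). The core pluripotency network had a mean of −0.02 with L1td1 at −0.15 and Jam2 at 0.19 (adjusted p = 0.808), and epithelial genes a mean of 0.00 with Perp at 0.04 and Krt19 at −0.01 (adjusted p = 0.891). The highest adjusted p was 0.953, for neural genes. Mean, median and test differed in sign for the reprogramming factor, epithelial and endothelial lists.

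The knockdown effect on pluripotency and epithelial genes differed between days as a group, but for single genes only when adjusted over the list alone. The mean difference of log2 fold changes, day 6 minus day 3, was 0.24 for the pluripotency network, with 36 of 42 members positive (adjusted p = 1.56e-08, and 0.00391 with an estimated correlation). It was 0.24 for epithelial genes, with 28 of 36 positive (adjusted p = 1.30e-07, and 0.0139 with an estimated correlation). No member passed over all genes, and adjusted over the list alone 7 pluripotency and 5 epithelial genes did. In limma 0 genes passed, against 910 at an unadjusted p of 0.05. The 5 highest-ranked positive differences were Nanog (0.64, adjusted p = 0.0978), Sall4 (0.81, 0.137), Cdh1 (1.03, 0.428), Tdgf1 (1.63, 0.786) and Car2 (1.56, 0.853). The 5 negative were Gapdhs (−0.62), Car11 (−0.59), Prrt4 (−0.43), Efcab15 (−0.51) and Trim43c (−0.56). Without day 6 knockdown replicate 1, 1 gene passed, Tdgf1 (adjusted p = 0.00102). The lists of chaperones, DNA replication, mitosis, interferon-stimulated and DNA methylation genes also passed, but none did with an estimated correlation (adjusted p = 0.441, 0.512, 0.512, 0.512 and 0.294). Of the other lists none passed, and mean, median and test differed in sign for the factor, neural, muscle, adipocyte, keratinocyte and oxidative phosphorylation lists. Adjusted over all genes, the rise of the 7 day 6 genes was thus not shown to differ from day 3 for any of them over all arrays.

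Between day 3 and day 6, control cells changed widely and proliferation genes fell. In limma 3140 of 17860 genes passed, 1248 higher and 1892 lower, of which 83 rose and 47 fell at least 2-fold. The count was 2002 without day 6 control replicate 1. The largest rises were Aspn (log2 fold change 3.48, SE 0.46), Tac2 (3.03, SE 0.16), Apela (2.93, SE 0.19), Abi3bp (2.78), Eln (2.33), which encodes elastin, Ecrg4 (2.21), Egfl6 (2.08), Jam2 (2.01), Ogn (1.98) and Apod (1.96). The largest falls were U90926 (−3.18, SE 0.14), Trh (−2.54, SE 0.23), Sprr2b (−1.87), Ptgs2 (−1.56), Nefl (−1.54), Lpl (−1.54), Cnn1 (−1.49), Tnfsf18 (−1.45), Fndc3c1 (−1.42) and Ankrd1 (−1.41). Adjusted p for these 20 genes was between 1.40e-07 and 0.00127, and their day 6 arrays did not overlap with their day 3 arrays. Over the alternatives Lpl ran from −1.68 to −1.01 and passed in each. The day 6 level of Tnfsf18 lay below the low-value filter in both time courses, so its falls were taken against background signal. The day 3 level of Aspn was 4.52 in control and 4.72 in knockdown arrays, above that filter but under the array medians. Its rises were thus taken from a level near background.

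In the same control cells 17 of 35 DNA replication genes and 19 of 31 mitosis genes fell and 0 rose, or 29 and 24 adjusted over the list alone. Examples were Rrm2 (−0.88), Mcm4 (−0.54), Ndc80 (−0.64) and Prc1 (−0.63). The means were −0.32 (adjusted p = 6.17e-11) and −0.37 (adjusted p = 2.30e-12), but with an estimated correlation the adjusted p was 0.631 for each. Chaf1a fell by 0.30 (adjusted p = 0.0419) and Chaf1b by 0.44 (adjusted p = 0.0107). Of 42 pluripotency genes 9 rose and 0 fell, by either count, including Jam2, Fbxo15 (1.28), Slc2a3 (0.60) and Tet1 (0.59). The mean was 0.18 (adjusted p = 0.0122, but 0.222 with an estimated correlation). Renewed quantile normalisation also ended that call (mean 0.16, adjusted p = 0.0885). Of 36 epithelial genes 5 rose, among them Spint1 (1.27), Cdh1 (0.96) and Spint2 (0.77), and 2 fell, among them Krt19 (−0.99), with the same counts adjusted over the list alone (mean 0.12, adjusted p = 0.0680).

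**Figure D3:**
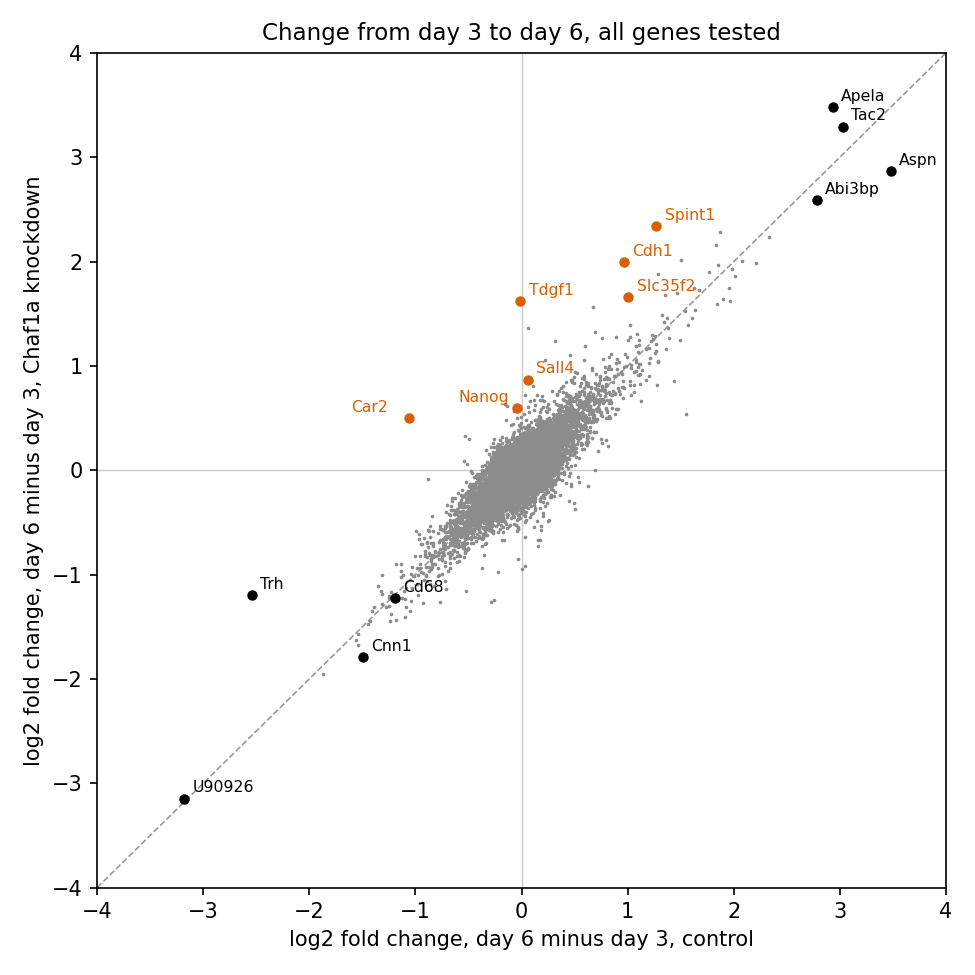
Log2 fold change from day 3 to day 6 in control (x axis) and in knockdown (y axis) for 17860 genes, with the 7 genes that passed the day 6 knockdown test in orange, other named genes in black and a dashed line of equality. Pearson's r across genes was 0.83, and Tdgf1 stood at 1.62 in knockdown.

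In knockdown cells the same interval brought a rise of pluripotency and epithelial genes. In limma 3200 genes passed, 1332 higher and 1868 lower, with 84 rising and 53 falling at least 2-fold. Of 42 pluripotency genes 16 rose and 0 fell, and 19 and 0 adjusted over the list alone, including Fbxo15 (1.88), Jam2 (1.86), Tdgf1 (1.62) and Nr0b1 (1.36). Tdgf1 lay below the low-value filter at day 3 in knockdown cells too, so its rise was taken against background signal. The mean was 0.42 (adjusted p = 8.69e-10, and 0.00242 with an estimated correlation). Of 36 epithelial genes 16 rose and 1 fell, and 19 and 1 adjusted over the list alone, including Spint1 (2.34), Cdh1 (1.99), Epcam (1.24) and Spint2 (1.06). The mean was 0.36 (adjusted p = 7.31e-07, and 0.0194 with an estimated correlation). The largest rises were Apela (3.48, SE 0.19), Tac2 (3.29, SE 0.16), Aspn (2.87, SE 0.46), Abi3bp (2.59), Spint1, Atp12a (2.29), Eln (2.23), Socs2 (2.16), Bex4 (2.01) and Egfl6 (2.01). The largest falls were U90926 (−3.15, SE 0.14), Sprr2b (−1.95), Cnn1 (−1.79), Lpl (−1.68), Ptgs2 (−1.62), Nefl (−1.57), Tnfsf18 (−1.47), Fndc3c1 (−1.45), Tll1 (−1.45) and Nabp1 (−1.44). Adjusted p for these 20 genes was between 1.29e-07 and 0.00112, and their arrays of the 2 days did not overlap. Over the alternatives Lpl ran from −1.85 to −1.07 and passed in each.

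Proliferation and chromatin genes also passed the list test in knockdown cells, but not with an estimated correlation. Of 31 mitosis genes 11 fell, and 14 adjusted over the list alone, among them Birc5 (−0.57) and Prc1 (−0.54) (mean −0.21, adjusted p = 5.23e-05, but 0.753 with an estimated correlation). Without day 3 knockdown replicate 1 the mitosis mean was −0.13 (adjusted p = 0.00730). Of 35 replication genes 4 fell, and 3 adjusted over the list alone, among them Rrm2 (−0.57) and Pola2 (−0.41) (mean −0.15, adjusted p = 0.00282, but 0.776 with an estimated correlation). Without the same array the replication mean was −0.08 (adjusted p = 0.128). Of 27 DNA methylation and heterochromatin genes 7 rose, and 8 adjusted over the list alone, among them Tet1 (1.06), Jarid2 (0.84) and Dnmt3b (0.60) (mean 0.16, adjusted p = 0.00741, but 0.539 with an estimated correlation).

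The control and knockdown time courses shared 824 rising genes, where independent lists would share 93.1, and 1259 falling genes, where they would share 198, and 0 genes moved in opposite directions. Across genes, which are not independent replicates, Pearson's r was 0.83 and Spearman's rho 0.70. Of the 7 genes higher in day 6 knockdown cells, 6 rose over time in knockdown cells. In control cells 3 rose and 1, Car2, fell. The 7 were chosen by the same day 6 arrays, which favours rises in knockdown cells and falls in control cells. The knockdown effects at day 3 and day 6 were almost unrelated across genes (r = 0.06, rho = 0.02), where simulation with unchanged groups gave r from −0.12 to 0.09. The day 3 effect correlated with the control time course at r = 0.17 (rho 0.22) and the day 6 effect at r = −0.17 (rho −0.25). Those comparisons share control arrays. Their covariances were 0.00474 and −0.00449, and simulation of unchanged groups that share the same arrays, without the pairing by replicate number, gave 0.00531 to 0.00860 and −0.00842 to −0.00471, so both observed values were smaller in size than these ranges. With each gene's own spread in each group, still without the pairing, the ranges were 0.00524 to 0.00823 and −0.00765 to −0.00373, and the second observed value lay within its range. With the mean correlation of same-number arrays, 0.216, put into the simulation, a step chosen after the result was seen, the ranges were 0.00378 to 0.00698 and −0.00664 to −0.00422, and both observed values lay within them.

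Averaged over both days, 0 genes differed between hairpins in limma, against 989 at an unadjusted p of 0.05 and 2 with the replicate block (smallest adjusted p without it 0.0724). Without day 6 knockdown replicate 1 the count was 2, and it was 1 without day 3 knockdown replicate 2 and 1 without day 6 knockdown replicate 2. The pluripotency network had a mean of 0.10 and epithelial genes of 0.12 (adjusted p = 2.52e-06 and 9.87e-08, and 0.0117 for each with an estimated correlation), with 0 members past the threshold and 6 and 7 higher adjusted over the list alone. Interferon-stimulated genes had a mean of 0.21 (adjusted p = 2.56e-05, but 0.864 with an estimated correlation), carried by day 3 knockdown replicate 2, without which it was 0.03 (adjusted p = 0.174). The fibroblast, cartilage and stress-response lists had means of −0.05, −0.06 and −0.05 (adjusted p = 0.0289 each, but 0.965, 0.482 and 0.809 with an estimated correlation). The highest adjusted p with an array left out was 0.863 for the fibroblast list (mean −0.01, without day 6 control replicate 1), 0.323 for cartilage (−0.04, the same array) and 0.248 for stress response (−0.04, without day 6 knockdown replicate 2).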

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

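In this part, the tests of the induced factors, of other cell types, of leukocytes, of the knockdown in every culture and of the proliferation genes at day 6 alone were chosen only after the result was seen.

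The knockdown effect on the core pluripotency network differed between days by 0.24 in mean log2 fold change (−0.02 at day 3, 0.22 at day 6), and that on epithelial genes by 0.24 (0.00 at day 3, 0.24 at day 6). Leukocyte, endothelial, keratinocyte, muscle and neural genes together shifted at day 6 by −0.002 (95% interval −0.07 to 0.06), where epithelial genes shifted by 0.24 (0.18 to 0.30). This was meant to weigh a lower share of fibroblasts that raised the markers of every other cell type alike. Markers of cell types absent from the cultures would stay near background whatever the share of fibroblasts. Whether those cells were present was not tested, so the shift cannot decide this. These lists cannot test a lower share of fibroblasts with more epithelial-like cells in their place, and that stays open. Fibroblast genes did lie lower, with a mean of −0.08, 38 of 40 members negative and 3 of 3 pairs lower (adjusted p = 0.00174, but 0.644 with an estimated correlation). Stronger induction of the factors in the knockdown arrays is a possible explanation: their mean log2 fold change was 0.0189 (−0.01 to 0.05), under the bound of 0.26 set for it, but it cannot be told apart from a direct effect of the hairpin, since every array was induced, Sox2 lay at 4.76 under the array medians, and the share of the signal that comes from the cassette is unknown. The knockdown, which the design names, stays open and untested as the cause, and Chaf1a itself was 1.09-fold lower at day 6 and not past the test.

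The knockdown effect on interferon-stimulated genes differed between days by −0.39 (0.40 at day 3, 0.01 at day 6; adjusted p = 6.31e-06, but 0.512 with an estimated correlation), and 1 array carried it: without day 3 knockdown replicate 2 the difference was −0.04 (adjusted p = 0.375). Interferon genes in that array exceeded those of the other day 3 knockdown arrays by a mean of 1.06 (95% interval over 26 genes 0.72 to 1.40), whereas 19 leukocyte genes, fixed as a list beforehand, exceeded them by 0.14 (0.07 to 0.22). Genes of 1 array are not independent replicates. The abundant leukocyte genes Laptm5 and Cd68 were at 8.93 and 9.05 there and at 8.91 to 8.97 and 9.04 to 9.16 in the other day 3 knockdown arrays. C1qb was at 6.32 against 5.79 to 6.04, and Spi1 at 6.20 against 5.95 to 6.08. This argues only against leukocytes that raised both lists alike. It cannot decide whether a few leukocytes induced interferon genes in the other cells. The other knockdown arrays exceeded the controls by 0.0497, within the control SD of 0.0542, and replicate 2 by 1.11. The knockdown thus showed no rise of that size in every culture, but this restates the pattern and is no separate test. The reason for an interferon response in that culture stays open, and the labels give nothing to test it with.

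Proliferation genes differed between days by 0.16 for DNA replication (−0.05 at day 3, 0.11 at day 6; adjusted p = 1.73e-07, but 0.512 with an estimated correlation) and by 0.16 for mitosis (−0.07 and 0.09; adjusted p = 4.95e-07, but 0.512). A day 6 control culture with low proliferation genes, replicate 1, was weighed for each part of this. Without it the differences between days were 0.09 for both lists and passed with the preset correlation (higher adjusted p = 0.00286). Without day 3 knockdown replicate 1 they were 0.23 and 0.24. At day 6 alone the means went from 0.11 to 0.04 and from 0.09 to 0.03 without control replicate 1, and neither passed. This leaves in knockdown replicate 1, which was low as well. Without replicate 1 of both groups the means were 0.07 and 0.06 and both passed with the preset correlation (higher adjusted p = 0.00324). The knockdown array was the higher in each remaining pair. Passes with the preset correlation do not measure the spread of list scores between arrays. They cannot decide whether that culture is the whole of the difference or of the day 6 shift. The knockdown stays open and untested as the cause, and neither list passes with an estimated correlation at day 3, at day 6 or in the difference. That test was run without the replicate block, so it leaves the pairing out.

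The knockdown effect on CAF-1 and other histone chaperones differed between days by 0.12 (−0.08 at day 3, 0.04 at day 6; adjusted p = 3.90e-04, but 0.441 with an estimated correlation). That on DNA methylation and heterochromatin genes differed by 0.13 (−0.06 at day 3, 0.07 at day 6; adjusted p = 1.02e-05, but 0.294 with an estimated correlation).

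The 6 arrays of a comparison can be split 3 against 3 in only 10 ways, so the share of splits with a count as large cannot go under 0.1. At day 6 the real split gave 7 genes, as did 1 of the 10 splits, itself, and the highest of the others gave 0. For the control time course the real split, 1 of 10, gave 3140 and the highest other 0, and for the knockdown time course it was 1 of 10 with 3200 against 0. At day 3 the real count was 0 and the highest other 1, and all 10 splits had to reach the real count, since none can go under 0. Because the replicate numbers pair the arrays, the real split is best compared with the 4 splits that part all 3 pairs, and the highest other among those was 0 in each comparison; the remaining splits put arrays of the same number in the same group. For the difference between days and the average over days the real count was also 0, so all 100 splits drawn reached it and the test decides nothing about chance. The highest other was 6 for the difference between days, or 2 among the 15 that part all pairs, and 5 for the average over days, also among those that part all pairs.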

How the results depend on the processing

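Leaving out replicate 2 of both day 3 groups or replicate 1 of both day 6 groups was chosen only after the result was seen; all other alternatives were planned, and all that were planned were run. The day 3 count was 0 in all 18 alternatives. The pluripotency and epithelial lists passed at day 6 in all 16 (means 0.20 to 0.23 and 0.21 to 0.26), and Chaf1a kept its sign and stayed short of the threshold in all 16 on each day. Renewed quantile normalisation or median centring moved the median of all genes by less than 0.1. Among the named genes and lists followed in each setting, the replicate block changed only the call of Spint1. It also changed the count for the average over days, and other genes were not followed one by one. With fry, of the lists called at day 3, at day 6 or in the difference between days, only the pluripotency and epithelial lists passed. Fry was run without the replicate block. In the knockdown time course fry did not pass for DNA replication (adjusted p = 0.188), mitosis (0.0888) and interferon-stimulated genes (0.369). That interferon call was also lost with the 50th percentile filter (0.244), median centring (0.0548) and array weights (0.0555), the leukocyte call with that filter (0.244), and the TGF-beta call with that filter (0.0765) and renewed quantile normalisation (0.113).

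For the day 6 count of 7, a fit of only the 2 groups compared gave 2, with fewer arrays to estimate the spread, an adjusted p of 0.01 gave 2, and leaving out arrays gave 2 to 8. For the average over days, with a count of 0, the replicate block gave 2, the intensity trend with robust estimation 2, array weights 3, and leaving out arrays 0 to 2. For the difference between days leaving out arrays gave 0 to 1. The control time course gave 568 genes at a minimum of 1.5-fold, 1520 at an adjusted p of 0.01 and 2002 to 2808 with an array left out, as fewer arrays or stricter thresholds would. The knockdown time course gave 588 and 1587 at those thresholds. Over all alternatives the highest counts were 3967 in control and 3514 in knockdown.

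Values near 0 changed sign, and the cause was not tested. The day 3 epithelial mean of 0.002 was −0.0092 with the 50th percentile filter, −0.0035 with array weights and −0.0177 to 0.0252 with arrays left out. With arrays left out Sox2 ran from −0.14 to 0.0221 at day 3 and from −0.0222 to 0.0911 at day 6, Klf4 from −0.0073 to 0.0623 and Myc from −0.10 to 0.0448 at day 6. The day 6 fibroblast mean ran from −0.17 to 0.0075. Counting each setting apart, day 6 genes other than Nanog fell short in 29 cases and called lists in 91, while Tdgf1 passed in the difference between days in 1. Signals near background, such as Sox2 and the control level of Tdgf1, limit how small a change can be read.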

Other observations

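The lists and tests of this part were all chosen before the result was seen. Between day 3 and day 6, Cnn1, Inhba, Smad7, Lpl and Pparg fell in both control and knockdown cells. Of 23 TGF-beta-responsive genes, 8 fell and 4 rose in control cells, or 10 and 4 adjusted over the list alone, with Cnn1, a smooth-muscle calponin, at −1.49, Inhba at −0.85, Smad7 at −0.69 and Tgfbi, which rose, at 0.68 (mean −0.20, adjusted p = 0.0621). In knockdown cells 10 fell and 4 rose, or 14 and 5 adjusted over the list alone (mean −0.22, adjusted p = 0.0187, but 0.700 with an estimated correlation and 0.0861 without day 6 knockdown replicate 3). The adipocyte genes Lpl and Pparg fell by 1.54 and 0.56 in control and by 1.68 and 0.44 in knockdown, in a list of 12 that was not called (adjusted p = 0.578 and 0.608). Of 19 macrophage and leukocyte genes, Cd68 fell by 1.19 in control and 1.23 in knockdown, while Laptm5 rose by 0.47 and 0.41 (means −0.20 and −0.24, adjusted p = 0.0680 and 0.0185). The knockdown call was lost with an estimated correlation (adjusted p = 0.539), without day 3 knockdown replicate 2 (0.0749) and without day 3 knockdown replicate 3 (0.0608).

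Metabolic and stress genes moved in both directions. Among 16 glycolysis genes Aldoc rose by 1.38 in control and 1.37 in knockdown, Slc2a3, a glucose transporter, by 0.60 and 1.19, and Pfkp fell by 0.95 and 0.90 (adjusted p of the list 0.555 and 0.953). The amino-acid synthesis gene Phgdh fell by 0.61 in control and 0.48 in knockdown, in a stress-response list with a mean of −0.10 (adjusted p = 0.0680) and −0.16 (adjusted p = 0.00380, but 0.423 with an estimated correlation). Cdkn2a, the senescence-associated cell-cycle inhibitor locus, rose by 0.53 and 0.63, and Igfbp3 by 0.57 and 0.40 (adjusted p of the list 0.313 and 0.735). The p53 target Sesn1 rose by 0.92 and 0.76, with its list not called (adjusted p = 0.788 and 0.537). Oxidative phosphorylation genes had means of −0.06 and −0.07 (adjusted p = 0.125 and 0.133).

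Single markers of other lineages also moved, and the endothelial, cartilage, neural, trophoblast, fibroblast, muscle, keratinocyte, germline, endoderm and two-cell-like lists were not called in either time course. The endothelial receptor gene Kdr rose by 1.00 in control and 1.25 in knockdown, and Sox6 of the cartilage list by 0.64 and 0.58, while Col2a1 fell by 0.64 and 0.77. Tubb3 of the neural list fell by 0.97 and 0.61, Gata2 of the trophoblast list by 0.91 and 0.82, and Pdgfrb of the fibroblast list rose by 1.11 and 0.91. Interferon-stimulated genes had a mean of 0.03 in control (adjusted p = 0.578) and −0.36 in knockdown (adjusted p = 0.0313, but 0.776 with an estimated correlation), and without day 3 knockdown replicate 2 the knockdown mean was −0.006 (adjusted p = 0.908). Mean, median and test differed in sign in control for the p53, DNA methylation, trophoblast, neural, muscle, adipocyte and keratinocyte lists, and in knockdown for the chaperone, senescence, neural, adipocyte and glycolysis lists.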
